A study of Mus musculus with 8 samples.

How the data were processed

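Total RNA from 8 samples of mouse bone marrow-derived dendritic cells was measured on one-colour Agilent arrays, 4 of immature cells on day 6 of culture and 4 of cells given LPS and collected on day 7. Per the labels, RNA was extracted with TRIzol, treated with DNase I and labelled with Cy3 using an Agilent Quick Amp kit. Per the file headers the arrays were read with Agilent Feature Extraction 11.0.1.1, and the values used are the deposited processed signals, an intensity with the background subtracted and spatial trends removed but not scaled between arrays. Per the file headers the deposited files also hold the raw median intensity of each spot and of its local background, the background-subtracted intensity, and other columns of flags, 0 or 1, for spots that were well above background, saturated or outliers. The background-subtracted intensities go below 0 while the processed signals are all positive, so the software raised dim signals to a floor above 0. The array design gives mouse positions on an older genome build than the annotation at hand, so no positions are reported.

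Spots carrying an outlier flag were left out (122 to 206 per array), the log2 processed signals of the spots of a probe were averaged, and the 75th percentile of each array's non-control spots was subtracted. Values are therefore log2 signals relative to that percentile. Of 55681 probes outside the controls, 27509 matched 1 gene symbol by transcript accession in a RefSeq gene table. The other 28172, of which 16194 were named by a chromosome interval, were kept apart. The matched probes covered 20887 genes, 5512 of them with more than 1 probe, and each gene was represented by the probe with the highest mean over the 8 arrays. A gene was tested when that probe was well above background on all 4 arrays of at least 1 group, which left 12706 genes.

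LPS-treated and immature arrays were compared with lmFit and eBayes, limma's moderated test (limma 3.58.1 and statmod 1.5.0 in R 4.3.3, with version 1.17.8 of data.table), two-sided, with p-values adjusted by the Benjamini-Hochberg method and called at an adjusted p of 0.05. A second count asked in addition for a log2 fold change of at least 1. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 21 gene lists and separately over the 13 marker lists, with an estimated correlation and the fry test as alternatives, and each list's members were also adjusted over the list alone. Where no probe of a gene was above background in one group, or a named gene's probe on only some arrays of a group, the change is given as a bound, with each dim value raised to the lowest level called well above background on its array. Array totals were compared with exact two-sided permutation tests. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.

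The comparison, the tests, the gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. The scaling to detected probes or spike-ins, the averaging of replicates 1 and 2 and the inclusion of unmatched transcripts were added afterwards. The rule names the 6 largest increases and 6 largest decreases among called genes above background on all 8 arrays with separated groups, and the 3 largest bounds in each direction. It adds from each gene list the 2 called members with the largest change in the commoner direction and the 1 with the largest in the other, and from each marker list the 1 called member with the largest change or, with none called, the member with the highest signal. It also names, whatever their result, Cd40, Cd80, Cd86, Cd83, Ccr7, Il6, Il12b, Il10, Tnf, Cd14, Tlr4, Itgax, Ciita, H2-Aa, Gapdh and Actb. Of the genes named by the rule, 1 is left out of the text. The gene lists covered costimulation and checkpoint ligands, the migratory mature dendritic cell module, MHC class II and class I presentation, cytokines, chemokines, chemokine receptors, interferon-stimulated genes, the NF-kB pathway and feedback, Toll-like receptor sensing, antigen uptake receptors, lysosome, glycolysis, oxidative phosphorylation and the TCA cycle, enzymes of nitric oxide, itaconate, tryptophan and prostaglandins, cholesterol synthesis, sterol efflux and lipid uptake, alternative activation, transcription factors, cell cycle, and survival and cell death. Marker lists covered dendritic cells, macrophages, monocytes, neutrophils, B cells, T cells, natural killer cells, plasmacytoid dendritic cells, mast cells and basophils, eosinophils, erythroid cells, megakaryocytes and platelets, and stromal cells and osteoclasts. Genes with no matched probe, such as Il12b, Mx1 and Mx2, were not analysed here. The closing section adds 14 gene families and 2 lists, of hypoxia response and ribosome biogenesis, written after the arrays had been compared.

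The labels number the replicates 1 to 4 in each group but do not say whether they are separate animals or cultures. They were counted as separate samples because the labels number them so. Replicates 1 and 2 of each group lay closest together, and no value here shows whether they are repeats of 1 sample, so averaging them, which leaves 3 against 3, is among the alternatives.

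The steps were tested on simulated data made from the arrays, 20 data sets with 200 changed genes each. A change of 0.5 log2 was recovered in 35.3% of genes, of 1 in 76.0% and of 2 in 96.5%, and 4.85% of calls were false. A list shifted by 0.5 log2 was called in 20 of 20 data sets, and 1 of 400 lists without a shift was called by camera. The simulated genes varied independently, so these list results do not cover lists whose genes move together. Far fewer genes were changed per data set than the 7124 called in the real data, so the rates of recovery and of false calls may differ there. The alternatives tried were another background correction (normexp with an offset of 50), quantile normalization, scaling to the median, to the detected probes or to spike-ins, no scaling, other filters, flags kept, other probe choices, another variance model, replicate numbers as a block, and leaving out each array in turn. The number of arrays limits the precision of every value.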

Results

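Gene expression was measured in dendritic cells grown from mouse bone marrow, before and after exposure to lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria that is sensed through Toll-like receptor 4. The labels describe monocytes from C57BL/6 females cultured with GM-CSF at 10 ng/ml and IL-4 for 6 days, giving immature dendritic cells. Mature cells were obtained by adding LPS at 50 ng/ml to the immature cells overnight, and were collected on day 7. There were 4 immature and 4 LPS-treated samples, each hybridised to its own one-colour array, and no cells were kept to day 7 without LPS. The labels put the LPS on top of a further night in culture, so the comparison covers both together.

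Each array held 59305 spots outside the controls. Between 47.7% and 51.3% of them were well above background on the immature arrays, and between 47.5% and 48.4% on the LPS arrays. The 75th percentile of the signal averaged 469 ± 18.5 (SD, n = 4) on the immature arrays and 406 ± 13.4 (SD, n = 4) on the LPS arrays, a difference removed by the scaling (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allows). The slope of the spike-in signals, per the file headers, was 0.947 ± 0.00743 (SD) on the immature and 0.973 ± 0.00925 on the LPS arrays (exact permutation p = 0.0286), a difference that subtracting a percentile leaves in place. No spot was saturated. All 8 arrays lay on 1 slide and were scanned together, with the immature samples in slide row 1 and the LPS samples in slide row 2, so the slide row and the treatment cannot be separated. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.12.

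The first principal component of the tested genes held 80.7% of the variance and separated the treatments, and the second held 8.31%. The second component parted immature replicates 1 and 2 (−22.2 and −21.5) from replicates 4 (12.9) and 3 (37.4), with replicate 3 at the far end. Its differences from the other immature arrays among bright genes had a spread (scaled median absolute deviation) of 0.254 to 0.387 log2, whereas the spread between the other immature arrays reached at most 0.204.

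**Figure D1:**
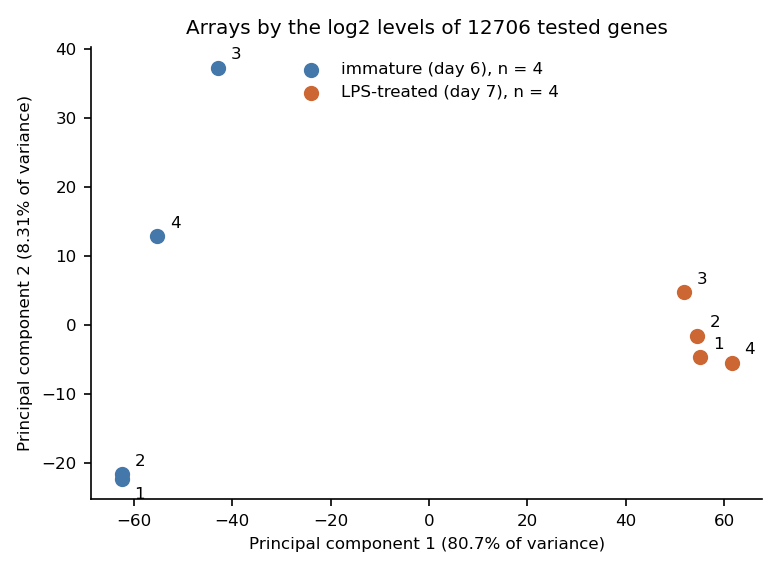
Principal components of the 8 arrays, from the log2 levels of the 12706 tested genes; each point is an array, numbered by replicate and coloured by treatment. The first component (80.7% of variance) parts the 4 immature from the 4 LPS-treated arrays, and the second (8.31%) parts immature replicates 1 and 2 from 3 and 4, with replicate 3 at the far end.

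The comparison of LPS-treated with immature cells asks how the transcriptome of dendritic cells changes as they mature. After LPS, 12 of 15 tested genes of costimulation, 25 of 27 of the migratory module, 16 of 21 cytokines and 34 of 34 interferon-stimulated genes rose. Limma's camera called these 4 lists at a preset correlation but not with an estimated one (adjusted p between 0.0843 and 0.100). Irf7, the transcription factor that amplifies type I interferon production, rose 80.6-fold and the cytokine gene Il6 48.1-fold. In the cell cycle list 28 of 29 genes fell, and in cholesterol synthesis 16 of 19 fell and 1 rose (limma adjusted p = 0.293 for both with an estimated correlation). The mannose receptor gene Mrc1, a C-type lectin of antigen uptake, fell by 4.23 ± 0.18 log2 (SE, n = 4 per group). Of 18 tested genes of MHC class I presentation 15 rose and 1 fell, and of 14 of MHC class II presentation 8 fell and 2 rose (limma adjusted p = 0.0968 and 0.316 with an estimated correlation). Of 14 tested marker genes of neutrophils and their granules 12 fell and 2 did not pass (limma adjusted p = 0.375 for the list with an estimated correlation), with Mpo at −4.66 ± 0.42 log2 (SE).

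Of 12706 genes tested with limma, 7124 (56.1%) changed at a Benjamini-Hochberg adjusted p under 0.05, 3988 upward and 3136 downward. At least 2-fold changes were found in 1163 rising and 1113 falling genes, and changes of 8-fold or more in 174 rising and 81 falling genes. The 4 LPS arrays lay entirely above or below the 4 immature arrays for 6654 tested genes (52.4%), where chance alone gives 2.86%; 6355 of these genes were among those called. Every named gene called changed was separated in this way except Ccl12 and Marchf1. The balance of directions depends on the scaling: 56.0% of the called genes rose here, against 38.5% (2615 rose, 4169 fell) when arrays were scaled to their median and 35.3% (2428 rose, 4445 fell) with no scaling. Those choices moved the median log2 fold change of all genes by −0.17 and −0.21 from 0.06, and the changes below are relative to the 75th percentile.

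The 6 genes with the largest increases among those measured on all 8 arrays were Irf7, Gp6, Saa3, Saa1, Cxcl5 and Il6. Irf7 rose by 6.33 ± 0.11 log2 (SE, n = 4 per group; limma adjusted p = 2.55e-08), from a level of −1.42 ± 0.09 (SD) to 4.91 ± 0.20 relative to the 75th percentile. Gp6, the collagen receptor known from platelets, rose by 5.89 ± 0.28. The acute-phase genes Saa3 and Saa1 rose by 5.86 ± 0.23 and 5.82 ± 0.21, and Saa3 reached a mean of 9.31 ± 0.13 (SD). The neutrophil-attracting chemokine gene Cxcl5 rose by 5.66 ± 0.27 and Il6 by 5.59 ± 0.28. The 6 largest decreases were in Asgr2, Klk1b9, Klk1b11, Klk1b3, Klk1b22 and Cyp2s1. Asgr2, a subunit of the asialoglycoprotein receptor, fell by 6.91 ± 0.35 (adjusted p = 2.35e-06), a 120-fold change. The 4 glandular kallikrein genes, members of 1 family, fell by between 5.26 ± 0.20 (Klk1b22) and 5.54 ± 0.23 (Klk1b9), and the cytochrome P450 gene Cyp2s1 fell by 5.15 ± 0.28.

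For genes below the detection limit in one group only a lower bound of the change can be given. Of the genes called changed, 78 were well above background on all 4 LPS arrays and on no immature array, with a median bound of at least 3.72-fold higher. The reverse was seen for 121 called genes, with a median bound of at least 1.84-fold lower. The lowest level called well above background was −5.00 to −4.34 on the immature arrays and −4.37 to −4.21 on the LPS arrays. A gene near that level could pass on the immature arrays alone without a fall, so these counts and medians cannot be set against each other. The largest bounds upward belonged to Nppc, encoding C-type natriuretic peptide (at least 35.4-fold higher), Kiss1, encoding kisspeptin (at least 33.9-fold higher, and at least 8.42-fold on its dimmer probe), and Plat, encoding tissue plasminogen activator (at least 31.9-fold higher). Downward they belonged to Cd209a, a C-type lectin gene related to human DC-SIGN (at least 38.2-fold lower, and at least 3.16-fold on its dimmer probe), Gsg1 (at least 11.9-fold lower) and the sodium-calcium exchanger gene Slc8a2 (at least 8.72-fold lower).

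Among costimulation and checkpoint ligands, which T cells read on the surface of dendritic cells, 12 of 15 tested genes rose, 2 fell and 1 did not pass. Adjusted over the list alone the counts were the same, 12 and 2. The median log2 fold change was 1.81 and camera called the list higher (adjusted p = 0.000695; adjusted p = 0.0843 with an estimated correlation). The largest increases were in Slamf1 (4.27 ± 0.24), a self-binding receptor of activated lymphocytes and dendritic cells, and Cd200 (4.09 ± 0.18), whose product restrains myeloid cells. The classical maturation markers Cd40 and Cd86 rose by 2.91 ± 0.21 (adjusted p = 1.60e-05) and 1.93 ± 0.11 (4.93e-06), and Cd83 rose from 4.89 ± 0.27 (SD) to 6.89 ± 0.28 (adjusted p = 4.09e-05). Icosl, the ligand of the T cell receptor ICOS, fell by 0.87 ± 0.19. Cd80 gave opposite answers on its 2 probes: the brighter probe, which represents the gene here, fell by 0.68 ± 0.09 (adjusted p = 0.000275), while the dimmer probe rose by 2.31 log2, and the mean of both rose by 0.82 (adjusted p = 0.000203). Probes called in opposite directions were found for 51 of 3292 genes with more than 1 tested probe, and Cd80 was the 1 member of the gene lists among them.

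The module of migratory mature dendritic cells, genes known to be shared by dendritic cells that travel to lymph nodes, had 25 of 27 tested members rising, 0 falling and 2 not passing, with 25 rising when adjusted over the list alone. Its median was 1.61 log2 (camera adjusted p = 1.27e-10; adjusted p = 0.0977 with an estimated correlation). Stat4, a transducer of interleukin-12 signals, rose by 3.49 ± 0.35 and the protease inhibitor gene Serpinb6b by 3.03 ± 0.28. Ccr7, the chemokine receptor that guides dendritic cells along lymphatics, had a level in the immature cells of 6.75 ± 0.40 (SD) and rose by 2.12 ± 0.18 (SE) to 8.87 ± 0.05 (SD; adjusted p = 3.64e-05).

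**Figure D2:**
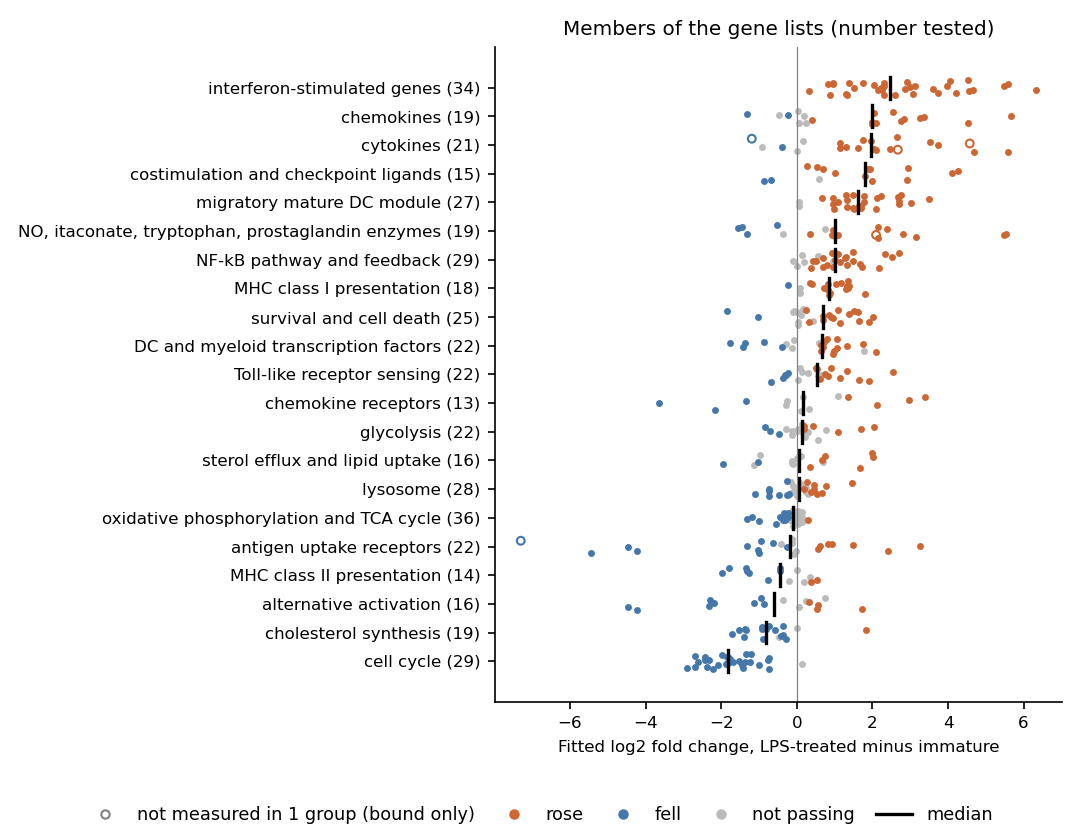
Fitted log2 fold change (LPS-treated minus immature, n = 4 per group) of each tested member of the 21 gene lists, with the median of each list as a black bar; orange, blue and grey points rose, fell or did not pass at adjusted p 0.05, and open points mark genes not measured in 1 group, for which only a bound is known. Medians run from −1.81 for the cell cycle to 2.46 for the interferon-stimulated genes, and those of the chemokine receptor, glycolysis, lysosome and sterol efflux lists change sign with no scaling between arrays.

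In the cytokine list 16 of 21 tested genes rose, 2 fell and 3 did not pass, with the same 16 and 2 when adjusted over the list alone. The median was 1.98 log2, or 1.76 with genes below detection in one group at their bounds (camera adjusted p = 0.000269; adjusted p = 0.100 with an estimated correlation). Il6 and Il1b, both early inflammatory cytokines, rose by 5.59 ± 0.28 and 4.69 ± 0.31. Il12a, encoding the p35 subunit of interleukin-12, was measured only after LPS and was at least 5.19-fold higher, and the type I interferon gene Ifnb1 at least 3.20-fold higher. Edn1, the endothelin-1 gene, was at least 1.43-fold lower, a call lost with the normexp background correction (−0.13, adjusted p = 0.129). Tnf did not pass at −0.91 ± 0.45 (adjusted p = 0.119), with 2.21 ± 0.94 (SD) in the immature and 1.30 ± 0.49 in the LPS-treated cells. Without immature replicate 3, which had the lowest immature level of Tnf, its log2 fold change was −1.33 (adjusted p = 0.00932). Il10 was not well above background on all 4 arrays of either group, and Il12b had no matched probe and was not analysed here.

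Of 19 tested chemokines 12 rose, 2 fell and 5 did not pass, again 12 and 2 when adjusted over the list alone. The median was 1.99 log2 (camera adjusted p = 0.00346; adjusted p = 0.212 with an estimated correlation). The neutrophil chemoattractant genes Cxcl5 and Cxcl1 led the list, Cxcl1 with 4.53 ± 0.60. The decrease of Ccl12, −1.33 ± 0.44 (adjusted p = 0.0315), no longer passed when any 1 of immature replicates 1 and 2 or LPS replicates 2, 3 and 4 was left out (adjusted p = 0.0780, 0.0778, 0.0545, 0.0588 and 0.0799) or replicates 1 and 2 were averaged (0.105). Chemokine receptors moved apart, with 4 of 13 rising, 3 falling and 6 not passing (4 and 3 when adjusted over the list alone), a median of 0.16 log2 that is −0.04 with no scaling, and camera adjusted p = 0.803. Cxcr5, the receptor for the follicle chemokine CXCL13, rose by 3.38 ± 0.11 and Ccrl2, a receptor that binds chemerin, by 2.98 ± 0.29. Ccr2, which brings monocytes out of the bone marrow, fell by 3.64 ± 0.34, and the monocyte marker list that holds it was not called (median −1.79, adjusted p = 0.110).

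All 34 tested interferon-stimulated genes rose, over all genes and when adjusted over the list alone, with a median of 2.46 log2 (camera adjusted p = 2.90e-17; adjusted p = 0.100 with an estimated correlation). Besides Irf7, Ifi44 rose most, by 5.58 ± 0.28. Of 29 tested genes of the NF-kB pathway and its feedback 23 rose, 0 fell and 6 did not pass (23 when adjusted over the list alone), with a median of 1.00. This list was called higher by camera (adjusted p = 1.93e-07) and was the 1 list of 21 still called with an estimated correlation (adjusted p = 0.0404). Traf1, an adaptor of TNF receptors, rose by 2.69 ± 0.09 and the phosphatase gene Dusp1 by 2.53 ± 0.32.

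The Toll-like receptor sensing list had 11 of 22 members rising, 5 falling and 6 not passing (12 and 5 when adjusted over the list alone), with a median of 0.54 and camera adjusted p = 0.0563. The missed call depends on the scaling: the list was called higher with scaling to the array median (adjusted p = 0.0215), to detected probes (0.0461) or to the spike-ins (0.0342) and with no scaling (0.0185). It was also called with the mean of a gene's probes (0.0435), with replicate numbers as a block (0.0473), and without immature replicate 3 (0.0310), LPS replicate 1 (0.0409) or LPS replicate 3 (0.0400). Cd14, the coreceptor that hands LPS to TLR4, rose by 2.54 ± 0.21, and Tlr1, which pairs with TLR2 to sense lipopeptides, by 1.92 ± 0.13. The adaptor gene Myd88 fell by 0.68 ± 0.19, a call lost when replicates 1 and 2 were averaged (−0.55, adjusted p = 0.0794). Tlr4 itself did not pass (0.55 ± 0.22, adjusted p = 0.0645), but passed without LPS replicate 1 (0.71, adjusted p = 0.0256) or LPS replicate 2 (0.67, adjusted p = 0.0451).

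MHC class I presentation, the route that shows peptides to CD8 T cells, had 15 of 18 members rising, 1 falling and 2 not passing (15 and 1 when adjusted over the list alone). Its median was 0.86 log2 (camera adjusted p = 5.16e-06; adjusted p = 0.0968 with an estimated correlation). The peptide transporter gene Tap1 rose by 1.81 ± 0.07 and Nlrc5, the transactivator of MHC class I genes, by 1.37 ± 0.12. The dimmer probe of Nlrc5 had 0.57 log2. The chaperone gene Canx fell by 0.24 ± 0.07 (adjusted p = 0.0158), a call lost without LPS replicate 1 (adjusted p = 0.0518), with replicate numbers as a block (0.0521), with spike-in scaling (0.0824) and with replicates 1 and 2 averaged (0.0976). For MHC class II presentation, 8 of 14 genes fell, 2 rose and 4 did not pass (8 and 2 when adjusted over the list alone), with a median of −0.45 (camera adjusted p = 0.0145; adjusted p = 0.316 with an estimated correlation). The peptide-loading genes H2-DMb2 and H2-DMa fell by 1.97 ± 0.11 and 1.81 ± 0.10, and Ciita, the master transactivator of class II genes, fell by 1.34 ± 0.24 (adjusted p = 0.00178). H2-Aa, encoding a class II alpha chain, fell by 0.75 ± 0.10 (adjusted p = 0.000318) from a high level of 7.11 ± 0.09 (SD). Marchf1, the ubiquitin ligase that removes class II and CD86 from the surface, rose by 0.53 ± 0.18 (adjusted p = 0.0315). That call was lost without immature replicate 3 or 4 (adjusted p = 0.0615 and 0.0816) or LPS replicate 3 or 4 (0.0731 and 0.0560). It was also lost with replicate numbers as a block (0.0805), with the mean of its probes (0.336), and with scaling to the array median (0.145), detected probes (0.0540) or spike-ins (0.0698) or no scaling (0.180), and the other Marchf1 probe had −0.27 log2.

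Receptors of antigen uptake were split: 10 of 22 fell, 7 rose and 5 did not pass (10 and 7 when adjusted over the list alone), with a median of −0.19 and camera adjusted p = 0.0570. The list was called lower with no filter on dim probes (adjusted p = 0.00153), with normexp background correction (0.0247), and without immature replicate 2 (0.0421), LPS replicate 3 (0.0400) or LPS replicate 4 (0.0437). The C-type lectin genes Cd209a and Cd209c led the decreases. Cd209c, measured on 3 of 4 LPS arrays, was at least 39.0-fold lower, and at least 3.85-fold on its dimmer probe. The scavenger receptor gene Marco, which binds bacteria, rose by 3.25 ± 0.24. Itgax, encoding the dendritic cell integrin CD11c, fell by 0.99 ± 0.10 (adjusted p = 8.89e-05). Among alternative activation genes, markers of cells exposed to IL-4, 8 of 16 fell, 4 rose and 4 did not pass (8 and 4 when adjusted over the list alone). The median was −0.61 (camera adjusted p = 0.0396; adjusted p = 0.212 with an estimated correlation). The call was lost without immature replicate 3 (adjusted p = 0.0703), with quantile normalization (0.0562), with scaling to the array median (0.112) or to detected probes (0.0712), with no scaling (0.125) and with replicates 1 and 2 averaged (0.0526). The lectin genes Clec10a and Mrc1 fell by 4.46 ± 0.32 and 4.23 ± 0.18, and the transglutaminase gene Tgm2 rose by 1.73 ± 0.11. In the macrophage marker list 5 of 9 genes fell and 1 rose (median −0.43, camera adjusted p = 0.0150; adjusted p = 0.375 with an estimated correlation).

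**Figure D3:**
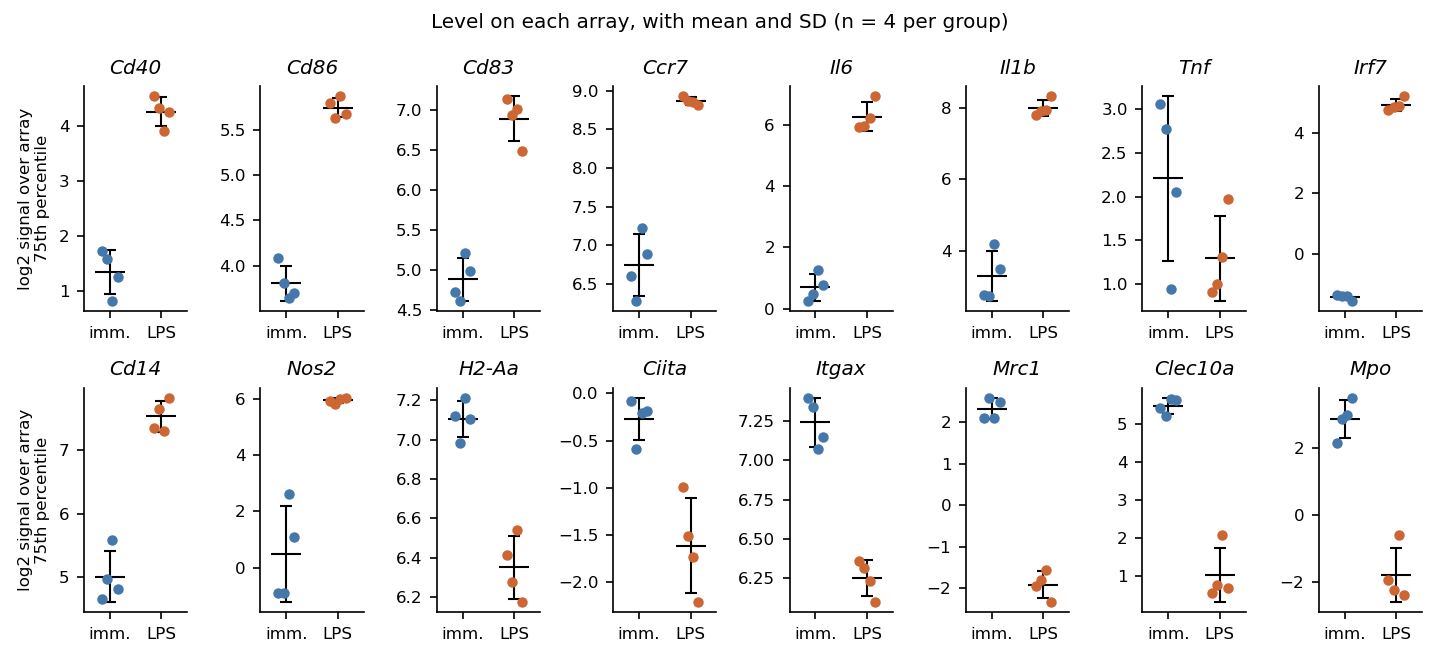
Level of 16 named genes on each array (log2 of the processed signal over the 75th percentile of its array; immature in blue, LPS-treated in orange; vertical scales differ), with the mean and SD of the 4 arrays per group. The groups do not overlap for any gene shown but Tnf, at 2.21 ± 0.94 and 1.30 ± 0.49.

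The enzymes that make nitric oxide, itaconate, tryptophan metabolites and prostaglandins included 13 rising, 4 falling and 2 not passing of 19 (13 and 5 when adjusted over the list alone), with a median of 1.01 (camera adjusted p = 0.0305; adjusted p = 0.114 with an estimated correlation). This call was lost with no filter on dim probes (adjusted p = 0.0807) and with genes limited to those above background on all 8 arrays (0.0930). Ptgs2, the inducible cyclooxygenase gene, rose by 5.53 ± 0.69 while Ptgs1, the constitutive one, fell by 1.55 ± 0.13. Nos2, the inducible nitric oxide synthase gene, rose by 5.47 ± 0.73, from levels that varied by 1.70 (SD) among the immature arrays to 5.94 ± 0.09. Ido1, which breaks down tryptophan, was at least 3.17-fold higher.

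In cholesterol synthesis 16 of 19 genes fell, 1 rose and 2 did not pass (16 and 1 when adjusted over the list alone), with a median of −0.82 (camera adjusted p = 2.60e-05; adjusted p = 0.293 with an estimated correlation). Fdps, which makes farnesyl diphosphate, fell by 1.52 ± 0.19. The phosphomevalonate kinase gene Pmvk rose by 1.83 ± 0.10. The sterol efflux and lipid uptake list was not called (6 of 16 rose, 2 fell, 8 did not pass; 6 and 2 when adjusted over the list alone; median 0.05, and −0.15 with no scaling; camera adjusted p = 0.609). Within it the lipid-binding gene Fabp4 rose by 2.01 ± 0.31, the cholesterol exporter gene Abca1 rose by 1.98 ± 0.28, and the nuclear receptor gene Pparg fell by 1.94 ± 0.23.

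The lists of energy metabolism had small medians. Of 22 glycolysis genes 6 rose, 3 fell and 13 did not pass (6 and 3 when adjusted over the list alone), with a median of 0.15, which is −0.06 with no scaling, and camera adjusted p = 0.666. The immature arrays differed among themselves in this list, with medians of −0.17 and −0.20 relative to the immature mean in replicates 1 and 2 and 0.18 in both replicates 3 and 4. Pfkfb3, which drives the phosphofructokinase step, rose by 2.03 ± 0.36 and the enolase gene Eno2 by 1.71 ± 0.11. Pdk1, whose kinase inhibits pyruvate dehydrogenase, fell by 0.83 ± 0.26 (adjusted p = 0.0261), a call lost when any 1 of immature replicates 3 and 4 (adjusted p = 0.0586 and 0.0570) or LPS replicates 1, 3 and 4 (0.0566, 0.0575 and 0.0536) was left out. Of 36 genes of oxidative phosphorylation and the TCA cycle 11 fell, 1 rose and 24 did not pass (10 and 1 when adjusted over the list alone). The median was −0.11, which is −0.32 with no scaling (camera adjusted p = 0.0181, or 0.638 with an estimated correlation). The largest decreases were in the TCA cycle, in Fh1 (−1.32 ± 0.14) and Idh2 (−1.20 ± 0.08), while the succinate dehydrogenase gene Sdhd rose by 0.30 ± 0.07, a call lost with scaling to the array median (adjusted p = 0.262) or to spike-ins (0.0556), with no scaling (0.414) and with replicates 1 and 2 averaged (0.0568). The lysosome list had 9 of 28 rising, 8 falling and 11 not passing (9 and 8 when adjusted over the list alone). Its median (0.05, or −0.16 with no scaling) and mean (0.03) were positive whereas the direction of its camera test was down (adjusted p = 0.923). The cholesterol carrier gene Npc2 rose by 1.45 ± 0.10 and the protease gene Ctsd by 0.76 ± 0.08, and Tfeb, the transcription factor of lysosomal genes, had −1.10 ± 0.10 (adjusted p = 4.33e-05).

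Cell cycle genes fell almost without exception: 28 of 29 fell, 0 rose and 1 did not pass, with 28 falling when adjusted over the list alone. The median was −1.81 (camera adjusted p = 1.15e-09; adjusted p = 0.293 with an estimated correlation). The mitotic genes Ccnb2 and Cdc20 fell by 2.90 ± 0.49 and 2.70 ± 0.35. The list was also lower in immature replicate 3, at −0.56 from the immature mean, than in the other immature arrays, and the LPS arrays lay between −1.46 and −2.43. Of 25 genes of survival and cell death 15 rose, 2 fell and 8 did not pass (15 and 2 when adjusted over the list alone), with a median of 0.68 (camera adjusted p = 0.00346; adjusted p = 0.0968 with an estimated correlation). Tnfsf10, encoding the death ligand TRAIL, rose by 2.02 ± 0.27, the inflammatory caspase gene Casp4 by 1.92 ± 0.12, and the survival gene Bcl2 fell by 1.85 ± 0.25.

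Dendritic cell and myeloid transcription factors showed 12 of 22 rising, 5 falling and 5 not passing (13 and 5 when adjusted over the list alone), with a median of 0.66 and camera adjusted p = 0.252. Irf8, required for several dendritic cell lineages, rose by 2.09 ± 0.18 and Nfil3 by 1.76 ± 0.39, while Cebpa, a factor of granulocyte and monocyte precursors, fell by 1.76 ± 0.14. Of the control genes, Gapdh had 0.20 ± 0.06 (adjusted p = 0.0256), which turns to −0.01 with no scaling, and Actb 0.23 ± 0.06 (adjusted p = 0.0122). Neither passed under quantile normalization (adjusted p = 0.519 for Gapdh and 0.442 for Actb) with scaling to the array median (0.791 and 0.535), to detected probes (0.134 and 0.0624) or to spike-ins (0.177 and 0.125), with no scaling (0.932 and 0.811), or with replicates 1 and 2 averaged (0.135 and 0.0834). Gapdh also missed the threshold without any 1 of immature replicates 1 and 2 or LPS replicates 1, 2 and 3 (adjusted p between 0.0625 and 0.0727), with replicate numbers as a block (0.0755) and with the mean of its probes (0.766).

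Marker genes of other cell types were tested as 13 further lists, of which 3 were called lower and 0 higher by limma's camera. With an estimated correlation 0 were called and 0 had an unadjusted p under 0.05, while fry called 7 lower and 2 higher. Neutrophil markers fell most, with 12 of 14 lower, 0 higher and 2 not passing (12 when adjusted over the list alone) and a median of −2.36 (adjusted p = 4.81e-05; adjusted p = 0.375 with an estimated correlation). Mpo, the myeloperoxidase of primary granules, fell by 4.66 ± 0.42. Mast cell and basophil markers fell in 5 of 6 genes (5 when adjusted over the list alone; median −1.78, adjusted p = 0.0150; adjusted p = 0.375 with an estimated correlation), led by the IL-33 receptor gene Il1rl1 at −3.90 ± 0.23. Macrophage markers fell in 5 of 9 and rose in 1 (5 and 1 when adjusted over the list alone; median −0.43, adjusted p = 0.0150; adjusted p = 0.375 with an estimated correlation), with the complement gene C1qc at −2.31 ± 0.11. With no scaling between arrays the adjusted p of both the macrophage and the mast cell and basophil lists was 0.0509.

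The other marker lists were not called. Monocyte markers had 5 of 8 lower and 1 higher (5 and 2 when adjusted over the list alone; median −1.79, adjusted p = 0.110, and 0.0137 with no filter on dim probes), with the coagulation factor gene F13a1 at −3.78 ± 0.56. Eosinophil markers had 4 of 6 lower (4 when adjusted over the list alone; median −1.45, adjusted p = 0.110, but 0.0327 without LPS replicate 4 and 0.0137 with no filter on dim probes), with the ribonuclease gene Ear6 at −2.28 ± 0.39. Dendritic cell markers had 4 of 9 higher and 2 lower, the same when adjusted over the list alone, with a median of 0.14 that is −0.07 with no scaling (adjusted p = 0.862). Flt3, the receptor of a dendritic cell growth factor, rose by 2.65 ± 0.18. Stromal and osteoclast markers had 3 of 6 higher (3 when adjusted over the list alone; median 1.01, adjusted p = 0.110), with the proteoglycan gene Dcn, measured on 1 of 4 immature arrays, at least 10.0-fold higher. Megakaryocyte and platelet markers had 4 of 8 higher and 2 lower, the same when adjusted over the list alone (median 0.25, adjusted p = 0.652), and Gp6 belongs to this list. T cell markers had 5 of 9 lower and 1 higher, the same when adjusted over the list alone (median −0.51, adjusted p = 0.346), with Cd6 at −2.04 ± 0.33 and Cd3d at least 3.10-fold lower. Natural killer cell markers had 2 of 5 lower, and 2 when adjusted over the list alone (median −0.45, camera adjusted p = 0.150). The representing probe of Klrb1c was at least 1.35-fold lower, a call lost with normexp background correction (limma adjusted p = 0.0577). Its other probe went the other way, at 1.03 log2, and was well above background on 1 LPS array and no immature array. Plasmacytoid dendritic cell markers had 2 of 8 lower (2 when adjusted over the list alone; median −0.11, adjusted p = 0.383), with the kallikrein gene Klk1 at −4.12 ± 0.24. Erythroid markers had 2 of 4 higher and 1 lower, the same when adjusted over the list alone (median 0.19, −0.02 with no scaling, mean −0.09, adjusted p = 0.862), with the globin gene Hba-a1 at least 2.52-fold lower. Of 6 B cell markers 0 passed, over all genes and adjusted over the list alone (median −0.28, limma adjusted p = 0.346), and the member with the highest signal, Cd79b, had −0.27 ± 0.40 (adjusted p = 0.586).

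**Figure D4:**
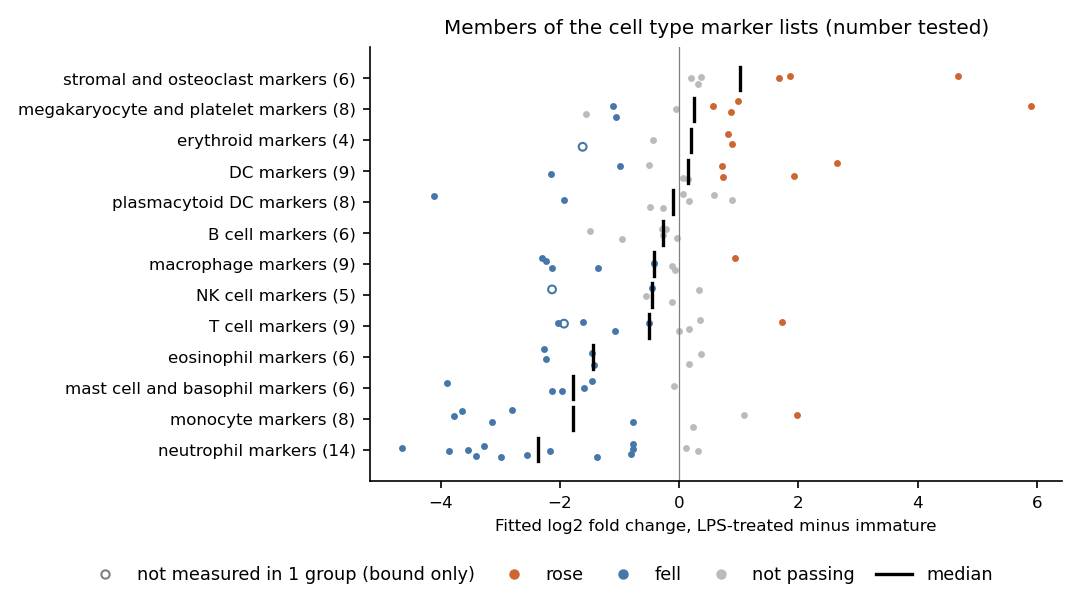
Fitted log2 fold change (LPS-treated minus immature, n = 4 per group) of each tested member of the 13 cell type marker lists, with list medians as black bars; orange, blue and grey points rose, fell or did not pass at adjusted p 0.05, and open points mark genes not measured in 1 group. Neutrophil markers have the lowest median, −2.36, and those of dendritic cell and erythroid markers change sign with no scaling between arrays.

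Camera compares the members of a list with all other genes at a preset correlation of 0.01; the fry test asks instead whether members move on balance one way, without comparing them with other genes, and its mixed form whether they change in either direction. Camera called 9 of the 21 gene lists higher and 5 lower, while fry called 13 higher and 6 lower. Without immature replicate 3 the count of changed genes was 7898 and that of changes of at least 2-fold 2570. Because LPS, the further day in culture and the slide row coincide, no value here separates them.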

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

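In this part the hypoxia, ribosome biogenesis, spread and interferon tests of immature replicate 3, the test of the spread between granule genes and the question of an untreated day-7 control were chosen only after the result was seen. A sample was singled out when its gap to the nearest of its group, as a share of the group's range, exceeded Dixon's critical value at 1 in 20. Of 276 groups of 4 arrays looked at (named genes and list medians in each treatment), 8 had such a sample, while 13.8 are expected by chance, so these 8 are no more than chance gives. Immature replicate 3 accounted for 3 of them.

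Immature replicate 3 stood apart in Eno2 (−1.88 against a mean of −2.23 in the other 3 arrays; gap 0.844 of the range), in Fh1 (4.70 against 5.26; 0.839) and in the median of the Toll-like receptor sensing list (0.21 against −0.06; 0.851). Pmvk was higher in immature replicate 4 (4.71 against 4.43; 0.869). Dcn was higher in immature replicate 1 (−3.64 against −6.48; 0.844), the 1 immature array on which it was well above background. Clec10a was higher in LPS replicate 3 (2.07 against 0.66; 0.876). In LPS replicate 4, Myd88 was higher (3.66 against 3.47; 0.871) and Gsg1 lower (−6.24 against −4.46; 0.931), at levels of Gsg1 below background. Among transcripts with no matched symbol, 32 named by a chromosome interval were well above background on all LPS arrays and on no immature array, and 128 showed the reverse. These are counts of detection, without a test of change. More spots were well above background on the immature arrays (mean 29696) than on the LPS arrays (28485.5), which by itself favours the reverse count. Of the tested transcripts named by an interval, 800 rose and 695 fell.

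Immature replicate 3 differed by more than 2-fold from the mean of the other immature arrays in 570 tested genes, 331 higher and 239 lower. A weaker array that lost its dim signals would leave bright genes as close as between the others, but its smallest spread among them was 0.254 log2, above the largest between the other 3, 0.204. Partial activation by LPS that includes interferon-stimulated genes is not borne out either. The array's position along the first principal component would need them 0.36 log2 higher. Their median deviation was 0.034 ± 0.075 (SE of the median over 34 genes of 1 array). That SE treats the genes as independent and does not cover variation between arrays. The medians of this list in immature replicates 1, 2, 3 and 4 were 0.10, 0.02, 0.03 and −0.10 relative to the immature mean. The cytokine list, however, was higher in immature replicate 3 than in replicates 1, 2 and 4 (median 0.34 against −0.16, −0.15 and 0.04). The chemokine list was lower (−0.21 against 0.08, 0.15 and −0.06). Of genes that rose after LPS, Nos2 and Il1b had their highest immature level in it, and Cd40 and Cxcl1 their lowest. A partial response without the interferon-stimulated genes is therefore not excluded. After genes such as Egln3 and Vegfa were seen among the largest deviations of immature replicate 3, a list of other textbook hypoxia targets was tested. All 26 tested members were higher in it (median 1.096, above every one of 10000 random lists matched on level). Of 25 ribosome biogenesis genes 24 were lower (median −0.89, below every random list). The random lists drew genes singly, so they do not cover lists whose genes move together. The hypoxia list followed from deviations of the same array, so its rank is no independent support. Of the 25 ribosome biogenesis genes 23 also fell after LPS, so their lower level is not particular to a shortage of oxygen. A culture short of oxygen with less ribosome production stays a candidate explanation only. Vegfa was 3.76 in immature replicate 4, against 1.27 and 1.70 in replicates 1 and 2 and 4.73 in replicate 3. Replicate 4 may hold a lesser form of the same pattern.

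Of 14 tested granule and marker genes of neutrophils 12 fell after LPS, with log2 fold changes of the 14 from −4.66 (Mpo) to 0.31 (Mmp9, not passing), and the list lost its call with an estimated correlation (limma adjusted p = 0.375). A lower share of granulocyte-lineage cells would by itself lower all 14 tested members alike. Their log2 fold changes had an SD of 1.58, where the median standard error of a member was 0.20, but other cells in the culture that express a member would hold its level up, so the uneven falls do not exclude such a loss. Of the members 1, Cxcr2, is also in the chemokine receptor list. The scaling between arrays is not the cause, as the list median was −2.57 with no scaling. With arrays scaled to the spike-ins, which moved the median of all genes by only −0.02, the list median was −2.38. The extra day in culture and LPS cannot be told apart here, since there were 0 arrays of untreated cells at day 7, and a change in maturation of these cells stays open as untested.

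All 14 tested members of the glandular kallikrein family around Klk1 fell, by between 2.37 and 5.54 log2. Their sequences are alike, so 1 transcript hybridising to every probe could account for the pattern. The deviations from the group means had a median correlation across the 8 arrays of 0.766 between members, above every one of 10000 random sets of 14 other genes that fell 4-fold or more (random median 0.242) but below the 0.9 set beforehand for a single source. Shared hybridization and a joint fall of several genes cannot be told apart with these probes. No biological explanation was tested.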

How the results depend on the processing

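The scaling to detected probes or spike-ins, the averaging of replicates 1 and 2 and the inclusion of unmatched transcripts were chosen after seeing the data; the other alternatives were planned. With no filter on dim probes 10758 genes changed (7627 rose, 3131 fell) in place of 7124, over 20883 genes tested. The median log2 fold change of all genes was then 0.26, against 0.06 with the filter. The median spot signal was 19.8 to 20.5 on the immature and 19.0 to 20.3 on the LPS arrays. The 75th percentile averaged 469 and 406, so subtracting it raises dim spots of like signal after LPS. How many of the added rising genes come from this was not tested. With an estimated correlation 1 gene list was called in place of 14; the cause was not tested. Gapdh reversed to −0.00804 with no scaling (limma adjusted p = 0.932, with 0.00201 to 0.932 over its alternatives), because the scaling shifts all genes. Cd80 reversed to 0.818 with the mean of its probes (limma adjusted p = 0.000203), because its 2 probes disagree. Leaving out each array in turn gave 6181 to 7898 changed genes, 2194 to 2570 changed at least 2-fold and 14 to 16 called lists.

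In the other alternatives 5425 to 9114 genes changed, or 10106 with unmatched transcripts included, and the count at 2-fold or more was 1604 to 3134. For single lists 727 of 781 values kept their direction and side of the threshold, 26 lost the call and 28 gained it; for single genes 1971 of 2026 did, 50 lost the call, 3 gained it and 2 reversed. With replicate numbers as a block 6606 genes changed, 2275 by at least 2-fold, and 15 lists were called; same-number arrays had deviation correlations across genes of −0.10 to 0.19 and 3 of 8 arrays correlated best with their own number, so the numbers were not treated as pairs.

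Leaving out saturated spots was not run, as 0 spots were saturated, nor was a slide or scan block, as all 8 arrays shared 1 slide and 1 scan. The normexp correction used median spot signals, as mean spot signals were not used here. Genes below background have no measured change, which limits Il10 and the genes given as bounds.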

Other observations

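The 14 gene families and the 2 lists in this part were chosen after the arrays had been compared; the counts of splits at the end were planned. Of 8 Schlafen genes, regulators of growth and viral RNA in leukocytes, 7 rose and 0 fell (7 when adjusted over the list alone), with a median of 2.09 log2 (camera adjusted p = 0.00123; adjusted p = 0.549 with an estimated correlation), and Slfn4 rose by 4.91 ± 0.23 (SE, n = 4 per group). Of 12 PARP enzymes, which attach ADP-ribose, 9 rose and 2 fell (median 1.02, adjusted p = 0.0110; adjusted p = 0.549 with an estimated correlation), led by Parp10 at 2.25 ± 0.13, while Parp1, of DNA repair, fell by 0.51 ± 0.09. Guanylate-binding proteins (7 of 10 higher, 1 lower, median 0.95) and TRIM proteins (18 of 41 higher, 6 lower, median 0.27) both had adjusted p = 0.0344 and adjusted p = 0.549 with an estimated correlation; 17 TRIM genes did not pass, and the TRIM call was lost without LPS replicate 4 (adjusted p = 0.0508). Of these families, 3 guanylate-binding proteins, 1 TRIM gene and 1 PARP enzyme are also in the interferon-stimulated list, and no test left them out. In the proteasome core 11 of 17 genes rose, 3 of the 17 being also in the MHC class I list (median 0.31, adjusted p = 0.0344; adjusted p = 0.550 with an estimated correlation), but 2 rose and 1 fell with no scaling (adjusted p = 0.155), and the call was also lost with quantile normalization (0.0827), scaling to the array median (0.123) or to spike-ins (0.0724), and without immature replicate 3 (0.0971) or LPS replicate 2 (0.0543). These medians stayed positive under all 6 scalings, but with no scaling that of the TRIM proteins was 0.07, with 15 higher and 9 lower.

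Of 25 ribosome biogenesis genes 23 fell and 0 rose, with a median of −1.10 (camera adjusted p = 7.14e-08; adjusted p = 0.430 with an estimated correlation), such as Wdr12 at −2.13 ± 0.27 and Ppan at −1.86 ± 0.37. Of 83 cytosolic ribosomal proteins 48 fell, 2 rose and 33 did not pass (50 and 2 when adjusted over the list alone). Their median was −0.28 (camera adjusted p = 1.49e-06, or 0.549 with an estimated correlation), and Rpl3 fell by 0.83 ± 0.09. With no scaling the median was −0.49, with 66 lower and 1 higher. Of 18 aminoacyl-tRNA synthetases, which charge tRNAs, 12 fell and 1 rose (median −0.35, adjusted p = 0.0110; adjusted p = 0.549 with an estimated correlation), with Vars at −1.40 ± 0.11. Minichromosome maintenance and origin factors, most of which act in DNA replication, fell in 13 of 19 and rose in 1, with 6 also in the cell cycle list. Their median was −0.70 (camera adjusted p = 0.00123, or 0.549 with an estimated correlation). These 4 medians stayed negative under all 6 scalings. Of 27 kinesins, 2 of them in the cell cycle list, 13 fell and 5 rose (median −0.25, adjusted p = 0.0747, but 0.0477 with the spike-ins and 0.04995 without LPS replicate 4). The hypoxia list had 3 higher, 3 lower and 20 not passing (median 0.25, adjusted p = 0.703), and its median depends on single immature arrays, with 0.01 and 0.06 without replicates 1 and 2 and 0.44 and 0.39 without replicates 3 and 4.

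The remaining families went both ways and were not called. Of 9 Clec4 lectins 3 rose and 3 fell (median −0.39, adjusted p = 0.398), Clec4e, the Mincle gene, by 2.14 ± 0.22 and Clec4a4 by −2.72 ± 0.24. Of 8 MS4A genes 4 rose and 2 fell (median 0.26, mean −0.13, adjusted p = 0.659). Of 7 CD300 receptors 2 rose and 3 fell (median −0.32, adjusted p = 0.530), and of 10 clade B serpins 5 rose and 2 fell (median 0.61, adjusted p = 0.130, but 0.0404 with no scaling and 0.0480 with scaling to the array median). Of 4 metallothioneins 2 rose and 1 fell (median 0.20, −0.01 with no scaling, adjusted p = 0.656).

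Transcripts with no matched symbol moved as well. Of 4424 tested transcripts named by a chromosome interval 800 rose and 695 fell, 286 and 269 of them by at least 2-fold, and of 4885 other unmatched transcripts 893 rose and 1317 fell. What these transcripts are was not analysed here.

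Of the 35 ways to split the 8 arrays into 4 and 4, only 1, the real one, gave as many changed genes (7124). Likewise only 1 gave as many changed at least 2-fold (2276). Every other split mixes LPS-treated and immature arrays. A rank of 1 in 35 is the lowest that 8 arrays allow, so chance is unlikely for both counts where the 8 arrays are separate samples. If replicates 1 and 2 of each group were repeats of 1 sample, the splits would be too few to say so. With limma the highest count in any other split was 0, and at an unadjusted p under 0.05 it was 2434, against 7786 in the real split.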
